A study of Mus musculus with 14 samples.

How the data were processed

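Neuronal nuclei from the medial entorhinal cortex of young and aged mice were profiled by SmartSeq RNA sequencing after TRIzol and chloroform extraction, per the labels' protocols. Groups were taken from the labels (7 young and 7 aged libraries), and libraries are named by group and title number. STAR, kallisto, DESeq2 and the build mm10 are named in the submitters' processing notes without versions or roles; the annotation, filters, model terms and the sex of the mice are not given in the sources used here.

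The authors deposited a single table with 27781 named gene rows and 1 row without a name, which holds 0.043 to 0.221% of a library's total and was left out. Of the gene names, 27 had been turned into dates by a spreadsheet and were kept as separate rows without being reassigned. The 14 library columns hold, per the file headers and the values, the authors' normalized signal per gene: the values are not whole, and the median ratio to the geometric mean is 1.023 in each library over 18245 genes above 0 in all libraries, the result of median-of-ratios scaling. Only 20.4 to 33.3% of low values lay within 0.05 of whole steps, against 10% by chance, so reads could not be recovered and depth is unknown; no count model and no counting interval was used. A baseMean column equals the mean of the 14 normalized values. The authors' log2 fold change and its standard error (aged over young, log2 units, per the file headers), a test score deposited as a statistic, and the authors' p-value and adjusted p-value were used only as the authors' comparison; that p equals the upper tail of a chi-square distribution with 1 degree of freedom, the form of a likelihood ratio test. A further row, Recording, holds 1 number per library. No value column was left unmapped (0). The normalization equalizes the typical gene across libraries, so a change shared by most genes would not appear, and values of long and short genes are compared only within a gene.

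Because the table holds normalized values, limma 3.58.1 (R 4.3.3; lmFit and eBayes with a mean-variance trend) on log2(value + 1) replaced the count test that had been planned, with genes kept at a value of 1 or more in at least 7 libraries (24554 genes), age as the only term and the Benjamini-Hochberg adjusted p under 0.05 as the threshold. Differences are aged minus young on the log2(value + 1) scale, which understates the change of low genes. On simulated libraries with the measured spread (5 simulations, 200 of 24554 genes changed), the fit with age alone recovered 0.8, 14.8, 46.0 and 60.4% of genes changed 1.5-, 2-, 4- and 8-fold with 2.2 false calls per simulation; the fit with the library set recovered 3.2, 20.8, 54.8 and 74.4% with 3.2 false calls. The library sets were defined after the data were examined, from Xist and the first principal component, and the set term, the fits within sets and the permutations within sets were added then.

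The 33 gene lists, named with their results in the report, were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry. The rule for named genes was fixed at the same time: the 8 with the smallest p in each direction past the threshold whose symbols are not predicted or clone-based, up to 4 members per list that passed or else the 2 with the smallest p as values only, and Hapln4, Pvalb, Sst, Gad1, Slc17a7, Reln, Calb1, Fos and Arc. Some genes that the rule names are not reported here. Genes named from the adjusted p under 0.1, from the fit with the library set (over all genes or over a list alone), from the authors' table and for nuclear RNA, and Apoe, were chosen after their values were seen. Marker scores, the spread of libraries and the recording value were compared with two-sided exact permutation tests over all 3432 splits of the libraries, or over the 441 splits within the sets (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Correlations with the recording value used all orderings of the 7 libraries of a set. Coordinates, gene spans and transcript sequences come from GENCODE M21 on mm10, in which 26171 gene rows matched a single gene by symbol. The counting of overlapping and antisense genes is not given in the sources used here.

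Alternatives covered scaling, filters, pseudocount, thresholds, sample weights, covariates and leaving out each library. DESeq2, voom, TMM scaling and surrogate variable analysis need counts and were not run; equal totals, upper-quartile scaling and the first principal component of the residuals stood in for them.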

Results

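Gene expression was measured in neuronal nuclei isolated from the medial entorhinal cortex of mice, a parahippocampal area that holds grid cells and other neurons tuned to position. SmartSeq libraries were available from 7 young and 7 aged samples, and the study set these transcriptomes beside electrophysiological recordings. Values are the authors' deposited normalized values per gene, so the read depth of a library is unknown. In each library 21152 to 25615 genes were above 0. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these samples. The deposited table also gives a single number per library, named Recording, without a unit.

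The 14 libraries formed 2 sets that did not follow age. Xist, the RNA that silences an X chromosome in female cells, lay at 18806 ± 6361 (SD, n = 7) in the libraries numbered 2 and 3 of the young group and 3, 4, 5, 6 and 7 of the aged group, and at 0.73 ± 1.93 (SD, n = 7) in the libraries numbered 11, 16, 17, 18 and 19 of the young group and 12 and 13 of the aged group. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y summed to 1.1 to 11.1 in the first set and to 4367 to 9425 in the second. The sets are called Xist-positive (2 young and 5 aged libraries) and Xist-negative (5 young and 2 aged libraries). They separated on the first principal component, which held 69.6% of the variance. With age in the model, 12776 of 24554 genes tested differed between them at an adjusted p under 0.05 in limma. Neither sex nor batch is given in the labels. Xist-positive libraries had fewer genes above 0 (21152 to 22812 against 25263 to 25615) and less Malat1, a nuclear long non-coding RNA (15723 ± 4035 against 115335 ± 43092, SD, n = 7 each). Meg3, another such RNA, had a higher mean in the Xist-positive libraries, with overlapping ranges (204151 ± 70107 against 155005 ± 38100, SD, n = 7 each). Nuclear RNAs therefore did not move together between the sets. Because the sets hold unequal numbers of young and aged libraries, age differences are given over all libraries and, where a pair of values is given, then with the library set in the model.

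**Figure D1:**
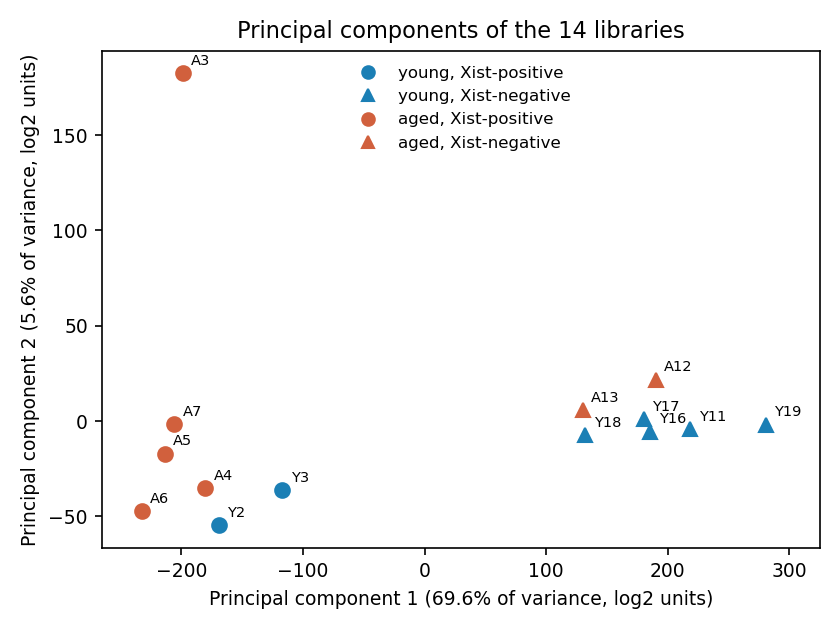
First and second principal components of the log2 values of the 14 libraries, in log2 units; blue marks young (Y) and orange aged (A) libraries with their title numbers, circles the Xist-positive and triangles the Xist-negative libraries. The 7 Xist-positive libraries lie below 0 and the 7 Xist-negative libraries above 0 on the first component, which holds 69.6% of the variance, and aged library 3 lies apart on the second at 182.

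The first comparison asked which genes differ between young and aged entorhinal neuronal nuclei. Sh3d19 (chromosome 3, 85971109 to 86130526, plus strand, mm10), which encodes an SH3-domain protein, was lower in aged libraries, at 1353 ± 389 against 4143 ± 1083 in young libraries (SD, n = 7 each). Every aged library lay below every young one, from 1062 to 2157 against 2251 to 5426. Its log2 difference, aged minus young on the log2(value + 1) scale, was -1.61 (SE 0.21, limma adjusted p = 0.0247) over all libraries and -1.68 (SE 0.23, adjusted p = 0.0369) with the library set in the model. It was -1.96 in the Xist-positive libraries and -1.40 in the Xist-negative ones. Rnf187, a RING-finger ubiquitin ligase gene (chromosome 11, 58932288 to 58938916, minus strand), was higher in aged libraries with the set in the model (log2 difference 1.93, SE 0.28, adjusted p = 0.0434). It measured 4781 ± 1384 in aged against 1050 ± 1020 in young libraries (SD, n = 7 each), and over all libraries its difference of 2.54 (SE 0.41) did not pass (adjusted p = 0.0562).

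Sh3d19 was the only gene past an adjusted p of 0.05 among the 24554 tested over all libraries, where 5920 genes had an unadjusted p under 0.05. With the library set in the model Sh3d19 and Rnf187 passed, and 3207 genes had an unadjusted p under 0.05. The Sh3d19 call was lost when any of 9 of the 14 libraries was left out. Over the 14 cases its adjusted p ran from 0.00292 to 0.108. No gene passed with the set in the model and aged library 3 left out, where Sh3d19 had a log2 difference of -1.65 (adjusted p = 0.0536).

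At an adjusted p under 0.1, 37 genes were higher and 4 lower in aged libraries, and all 41 had the same sign with the library set in the model. The balance differed between fits: at the same threshold 27 were higher and 17 lower with the set in the model, 4 higher and 81 lower in the Xist-positive libraries, and 6 higher and 5 lower in the Xist-negative ones. The genes named from this threshold were chosen after the values were seen. Txndc5, a protein disulfide isomerase of the endoplasmic reticulum, measured 1865 ± 460 in aged and 777 ± 172 in young libraries (SD, n = 7 each), a log2 difference of 1.25 (SE 0.19, limma adjusted p = 0.0562) that was 1.15 with the set in the model. Minpp1, which dephosphorylates inositol phosphates, measured 1960 ± 192 against 1096 ± 204 (log2 difference 0.85, SE 0.14, adjusted p = 0.0648; 0.78 with the set in the model). Stim2, a calcium sensor of the endoplasmic reticulum, measured 5305 ± 2207 against 1742 ± 708 (log2 difference 1.62, SE 0.27, adjusted p = 0.0652; 1.42 with the set in the model). In these 3 genes every aged library lay above every young one. Tapt1 (1.91 and 1.61), Bag1, a co-chaperone of Hsp70 (2.34 and 1.95), Klhdc2, a substrate receptor of a ubiquitin ligase (1.44 and 1.07), and Pnrc1 (2.05 and 1.53) also had positive log2 differences in both fits, with adjusted p from 0.0562 to 0.0659 over all libraries. Apoe, the main lipid carrier secreted by astrocytes, measured 5785 ± 2098 in aged and 2261 ± 938 in young libraries (log2 difference 1.38, SE 0.26, adjusted p = 0.0795; 1.24 with the set in the model). On the lower side, Flna, an actin crosslinker, had a log2 difference of -0.81 (SE 0.16, adjusted p = 0.0981) and Hspbap1 of -1.08 (SE 0.22, adjusted p = 0.0978), against -0.82 and -0.97 with the set in the model. The 2 groups did not overlap in 52 of 24554 genes (0.212%, against 0.0583% by chance). The chance share treats the libraries as exchangeable and leaves out the library sets. Genes are also not independent, so the 2 shares are not a test.

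**Figure D2:**
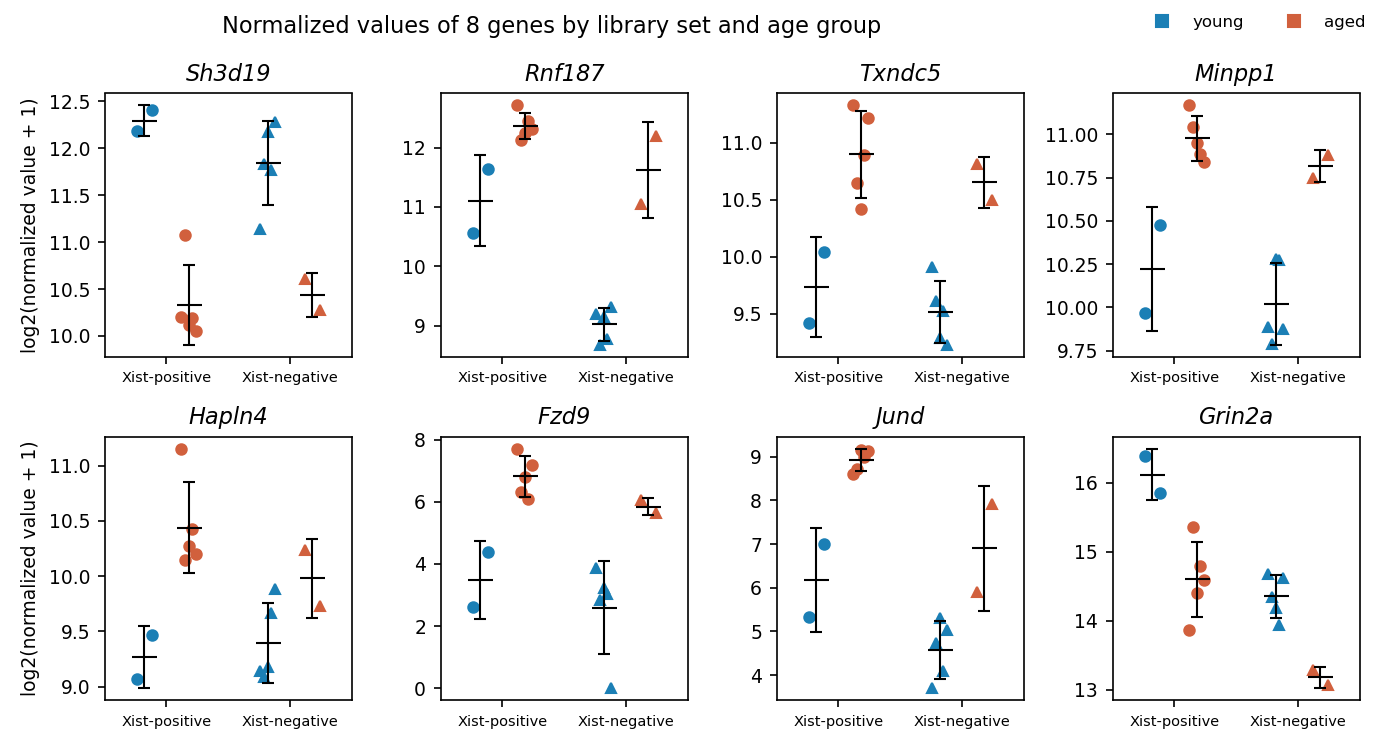
Normalized values of 8 genes on the log2(value + 1) scale in each library, split by library set (horizontal axis) and age group (blue, young; orange, aged), with circles for Xist-positive and triangles for Xist-negative libraries; black bars are the mean ± SD of 2 or 5 libraries. Sh3d19 and Grin2a are lower and the other genes higher on average in aged libraries within both sets.

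The authors' deposited table gives their own comparison of the age groups, in which 512 of 21253 genes with an adjusted p passed 0.05, 178 of them higher and 334 lower in aged mice. Sh3d19 led it with a log2 fold change of -1.68 (SE 0.25, adjusted p = 1.276e-07 in the authors' deposited table). Among genes with higher values in that table were Fzd9, a Wnt receptor (log2 fold change 3.13, adjusted p = 3.207e-06), Jund, a subunit of the AP-1 transcription factor (2.58, adjusted p = 3.207e-06), Rnf187 (1.93, adjusted p = 3.207e-06), Klhdc2 (1.10) and Txndc5 (1.15). Among genes with lower values in the authors' deposited table were the postsynaptic scaffold Shank1 (-1.10, adjusted p = 1.051e-05), the NMDA receptor subunit Grin2a (-1.33, adjusted p = 7.144e-05), the GTPase regulator Agap2 (-1.08, adjusted p = 0.000303) and the long non-coding RNA Miat (-0.78, adjusted p = 0.000231). The model terms behind the table are not given in the sources used here. Of its 512 genes, 478 had the same sign in the limma fit over all libraries (93.4%, 95% exact binomial interval 90.8 to 95.4%) and 512 with the library set in the model (100%, 99.3 to 100%). Both use the same libraries, so the shares are not independent evidence. Across 16230 genes with a mean of 100 or more, which are not independent replicates, the authors' log2 fold changes correlated with these fits at r = 0.673 and r = 0.937. The authors' fold changes thus followed the fit with the set in the model more closely than the fit with age alone. These values argue against age as the only term behind the authors' table, and which further term it held is not known. By limma 356 of the 512 genes had an unadjusted p under 0.05 over all libraries and 510 with the set in the model, but 41 and 42 an adjusted p under 0.1.

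Genes of protein synthesis, respiration and protein folding mostly had positive log2 differences, though no single member passed, over all genes or over its list alone. All 77 cytosolic ribosomal protein genes were positive over all libraries, with a median of 0.58 over all libraries, 0.41 with the library set in the model, 0.44 in the Xist-positive and 0.36 in the Xist-negative libraries. Of 46 nuclear-encoded genes of oxidative phosphorylation, 44 were positive, with medians of 0.63 and 0.43 in the same 2 fits. Of 24 chaperone and unfolded protein response genes, 22 were positive, with medians of 0.34 and 0.36. Against other genes, the camera test with a preset correlation called each list as higher (adjusted p = 5.467e-25, 1.478e-17 and 6.627e-06 over all libraries). The calls held in both fits and within each library set, while each list had an adjusted p = 0.276 over all libraries with an estimated correlation. Short genes as a whole also had positive values: in the shortest of 5 equal groups of genes by span the median was 0.24 over all libraries and 0.13 with the set in the model. Rpl18 had log2 differences of 1.03 and 0.81, Rplp0 of 0.69 and 0.56, and the complex III subunits Uqcrb of 0.87 and 0.68 and Cyc1 of 0.86 and 0.48. The chaperone Calr had log2 differences of 0.59 and 0.39 and the stress transcription factor gene Ddit3 of 0.91 and 0.63. The 13 mitochondrially encoded genes moved with the library set: their median was -0.39 over all libraries (camera adjusted p = 0.497) and 0.17 with the set in the model (adjusted p = 0.0914). The genes mt-Nd6 and mt-Nd5 had log2 differences of -1.42 and -1.10 over all libraries that became -0.28 and 0.07. The median log2 difference of all genes tested was -0.253 over all libraries and -0.157 with the set in the model.

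**Figure D3:**
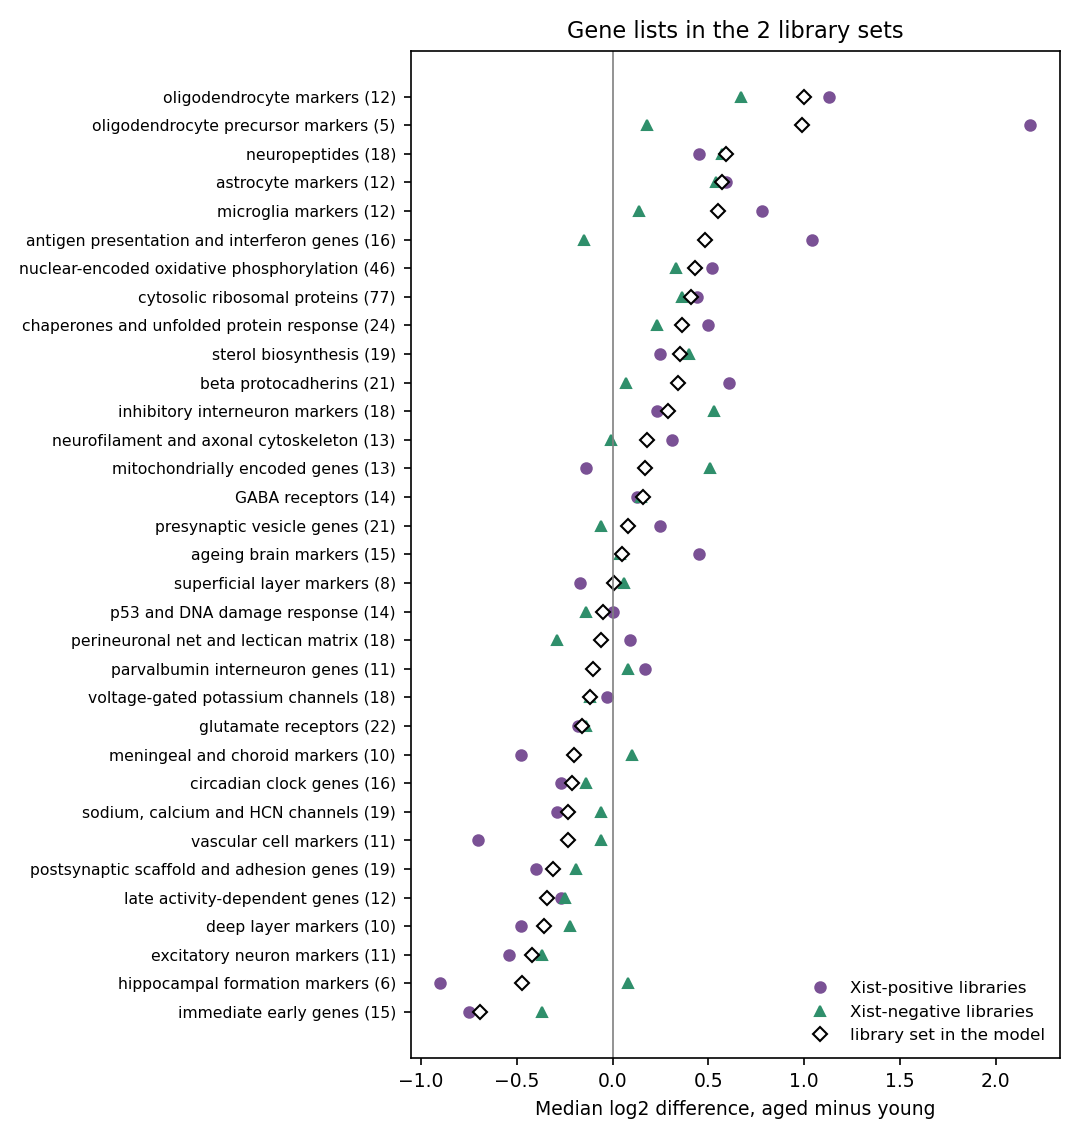
Median log2 difference, aged minus young, of the 33 gene lists (number of genes tested in parentheses) in the Xist-positive libraries (purple circles), the Xist-negative libraries (green triangles) and with the library set in the model (open diamonds). Ribosomal protein, oxidative phosphorylation, chaperone, sterol, astrocyte, oligodendrocyte and neuropeptide lists lie above 0 in both sets. Lists below 0 in both sets include immediate early genes, excitatory neuron and deep layer markers, and postsynaptic genes. The median of all genes tested is itself -0.134 in the Xist-positive and -0.148 in the Xist-negative libraries.

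Across the 33 lists, 15 were called over all libraries, all as higher, and 14 with the library set in the model, 13 as higher; 11 were called in both. With an estimated correlation no list passed in either fit (smallest adjusted p = 0.276 and 0.155), nor did fry call any (smallest adjusted p = 0.303 and 0.196), so the calls rest on the preset correlation of 0.01. Of 100 splits of the libraries, the real one included, 15 called at least 15 lists. Tests of single genes over their list alone were adjusted within each list and not across the 33 lists. No list member passed over all genes in either fit.

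Neuropeptide genes were called as higher, with positive log2 differences in 14 of 18 over all libraries and 17 of 18 with the set in the model, with medians of 0.43 and 0.59 (camera adjusted p = 0.000999 and 2.77e-05, against adjusted p = 0.276 and 0.155 with an estimated correlation). Sst, the somatostatin gene of a class of dendrite-targeting interneurons, measured 2242 ± 755 in aged and 1191 ± 504 in young libraries (SD, n = 7 each), a log2 difference of 0.97 (SE 0.31, adjusted p = 0.182; 0.89 with the set in the model). Vgf had log2 differences of 0.61 (adjusted p = 0.182) and 0.57. The 18 inhibitory interneuron markers had medians of 0.12 and 0.29 (camera adjusted p = 0.0366 and 0.00663, against adjusted p = 0.276 and 0.294 with an estimated correlation), with 10 and 12 positive. Slc32a1, the vesicular GABA transporter, had log2 differences of 0.96 (adjusted p = 0.262) and 0.60. Gad1, a GABA-synthesizing enzyme, had differences of 0.16 (SE 0.25, adjusted p = 0.700) and 0.30, and Pvalb, the parvalbumin gene of fast-spiking interneurons, of 0.26 (SE 0.74, adjusted p = 0.839) and -0.14. The 11 parvalbumin interneuron genes were not called (medians 0.33 and -0.10, adjusted p = 0.121 and 0.177), with Kcnc1 at 3868 ± 2755 in aged and 1628 ± 1243 in young libraries (SD, n = 7 each; log2 difference 0.31 with the set in the model) and Erbb4 at log2 differences of 0.47 and 0.58.

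Hapln4, a link protein of perineuronal nets, measured 1321 ± 450 in aged and 669 ± 159 in young libraries (SD, n = 7 each), a log2 difference of 0.95 (SE 0.21) that did not pass over all genes (limma adjusted p = 0.121) but did over the list alone (limma adjusted p = 0.00581). With the library set in the model it was 0.88 (SE 0.23), and it was 1.17 in the Xist-positive and 0.59 in the Xist-negative libraries. The log2 fold change in the authors' deposited table was 0.89 (adjusted p = 0.0370). Cspg5, a neural chondroitin sulfate proteoglycan, was the other matrix gene past the test adjusted over the list alone (log2 difference 0.81, limma adjusted p = 0.0152; 0.89 and 0.0117 with the set in the model). As a group the 18 perineuronal net and lectican genes were not called (7 positive, median -0.23, camera adjusted p = 0.785).

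Among synaptic genes, single members passed the test over their list alone. Gabra2, a GABA-A receptor subunit (chromosome 5, 70957597 to 71095849, minus strand), measured 3155 ± 1799 in aged and 9665 ± 4806 in young libraries (log2 difference -1.63, SE 0.40, adjusted p = 0.152, and limma adjusted p = 0.0120 over the list alone; -1.77 and 0.0119 with the set in the model). Gabra3 passed only with the set in the model (0.35 and 0.58, limma adjusted p = 0.376 and 0.0376 over the list alone). The 14 GABA receptor genes were not called (median 0.22, adjusted p = 0.0570). Shank1 had a log2 difference of -0.66 (limma adjusted p = 0.309 over the list alone) that became -1.09 with the set in the model (limma adjusted p = 0.000190 over the list alone). The 19 postsynaptic genes were not called (medians 0.00 and -0.31, adjusted p = 0.604 and 0.0813). Grin2a (chromosome 16, 9567898 to 9995560, minus strand) had a log2 difference of -0.66 over all libraries (adjusted p = 0.317, and 0.813 over the list alone) and -1.35 with the set in the model (adjusted p = 0.0776, and limma adjusted p = 0.000834 over the list alone). The 22 glutamate receptor genes were not called (medians -0.10 and -0.16, adjusted p = 0.340 and 0.875), with Grin2c at 2.15 and 1.37. The 21 presynaptic vesicle genes were called as higher over all libraries (16 positive, median 0.21, camera adjusted p = 0.0130, against adjusted p = 0.387 with an estimated correlation) and not with the set in the model (0.08, adjusted p = 0.354). Bsn and Unc13a, release-site scaffold and priming genes, had log2 differences of -0.63 and -0.51 over all libraries (adjusted p = 0.182 each) and -0.71 and -0.54 with the set in the model. With the set in the model Bsn and Rims1, another release-site scaffold gene (-0.67, against 0.00 over all libraries), passed as lower over the list alone (limma adjusted p = 0.0452 each).

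The 19 sodium, calcium and HCN channel genes had a median of 0.17 over all libraries (14 positive, camera adjusted p = 0.0348, against adjusted p = 0.646 with an estimated correlation) and of -0.23 with the set in the model (7 positive, adjusted p = 0.295). Cacna1d, an L-type calcium channel, measured 7712 ± 998 in aged and 11935 ± 2485 in young libraries (log2 difference -0.61, SE 0.17, limma adjusted p = 0.0394 over the list alone; -0.70 and 0.01005 with the set in the model). Scn2b had a log2 difference of 1.27 (limma adjusted p = 0.0489 over the list alone) that became 0.64 with the set in the model, where it did not pass (limma adjusted p = 0.0502 over the list alone). With the set in the model Cacna1b, Scn8a and Cacna1e passed adjusted over the list alone at -0.56, -0.59 and -0.73, against 0.07, 0.04 and -0.22 over all libraries. The 18 voltage-gated potassium channel genes had medians of 0.21 and -0.12 (camera adjusted p = 0.01001 and 0.875, against adjusted p = 0.490 over all libraries with an estimated correlation), with Kcnc4 at 0.41 and 0.20. The 13 neurofilament and axonal cytoskeleton genes had medians of 0.46 and 0.18 (adjusted p = 0.000292 and 0.0950, against adjusted p = 0.276 over all libraries with an estimated correlation), with Sptbn4 at 1.03 and 0.33 and Gap43 at 0.75 and 0.72.

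Of 15 immediate early genes, 14 had negative log2 differences in aged libraries, with a median of -0.42 over all libraries (camera adjusted p = 0.174) and -0.69 with the set in the model, where the list was called as lower (adjusted p = 0.0375, against adjusted p = 0.677 with an estimated correlation). Npas4, a transcription factor induced by neuronal activity, had a log2 difference of -1.48 (SE 0.48, adjusted p = 0.182), Arc, an activity-induced synaptic gene, of -1.09 (SE 0.48, adjusted p = 0.196) and Fos of -0.22 (SE 0.33, adjusted p = 0.678). With the set in the model these were -1.59, -0.96 and -0.33. The 12 late activity-dependent genes were not called (medians -0.04 and -0.34, adjusted p = 0.497 and 0.694). Of 16 circadian clock genes, Dbp, a clock output gene, had a log2 difference of 2.36 (SE 0.56, limma adjusted p = 0.00990 over the list alone) and Per2, a repressor of the clock, of -0.74 (SE 0.20, limma adjusted p = 0.0163 over the list alone). With the set in the model they were 1.70 and -0.70 (limma adjusted p = 0.0176 and 0.0285 over the list alone). Per1 had log2 differences of -0.71 over all libraries (limma adjusted p = 0.113 over the list alone) and -1.04 with the set in the model (limma adjusted p = 0.00650 over the list alone). The clock list was not called (medians -0.06 and -0.21, adjusted p = 0.944 and 0.295), and the labels give no time of tissue collection.

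Markers of other cell types were measured beside these lists. The 12 astrocyte markers were called as higher (medians 0.33 and 0.57, camera adjusted p = 0.000649 and 0.000149, against adjusted p = 0.276 and 0.344 with an estimated correlation). Aldoc had a log2 difference of 1.30 (SE 0.31, limma adjusted p = 0.00910 over the list alone) and Ntsr2 of 1.38 (limma adjusted p = 0.00985 over the list alone). Neither passed over all genes (limma adjusted p = 0.152 and 0.182). With the set in the model Aldoc was at 1.23 (limma adjusted p = 0.0305 over the list alone) and Ntsr2 at 1.04, where it did not pass (0.0506). The 12 oligodendrocyte markers were positive in 9 genes over all libraries and 12 with the set in the model (median 0.57 over all libraries, 1.13 and 0.67 within the sets; adjusted p = 0.0117 and 4.929e-07, against adjusted p = 0.619 and 0.372 with an estimated correlation), with the myelin genes Mbp at 0.96 and Mobp at 1.25 with the set in the model (limma adjusted p over the list alone 0.0497 each, against 0.0609 and 0.146 over all libraries). The 5 precursor markers (medians -0.78 and 0.99, adjusted p = 0.604 and 0.0154) and 12 microglia markers (0.17 and 0.55, adjusted p = 0.151 and 0.00101) were called only with the set in the model, and with an estimated correlation their adjusted p there was 0.400 and 0.442. C1ql1 had log2 differences of 1.77 and 1.63, Cspg4 of -1.26 and -0.15, and the complement genes C1qc of 0.71 and 0.98 and C1qb of 0.54 and 0.59, none past the test. Over their list alone, the precursor gene Pdgfra (0.80 and 2.35, limma adjusted p = 0.541 and 0.00663) and the oligodendrocyte gene Ermn (1.40 and 2.66, limma adjusted p = 0.523 and 0.0301) passed only with the set in the model. The 11 vascular markers (medians -1.07 and -0.23), 10 meningeal and choroid markers (-0.23 and -0.20), and 6 hippocampal formation markers (-0.88 and -0.47) were not called (adjusted p from 0.290 to 0.875). Kdr, Cdh5, Folr1, Col3a1 and Lct had log2 differences of -1.71, -2.09, -2.32, -3.35 and -1.78 over all libraries and -0.79, -0.54, -1.31, -2.15 and -0.75 with the set in the model. Dsp, a desmosomal gene of dentate granule cells, had a log2 difference of -3.15 (limma adjusted p = 0.0325 over the list alone) that became -1.70 with the set in the model (adjusted p = 0.131 over the list alone).

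Markers of excitatory neurons and of cortical layers were not called. The 11 excitatory markers had medians of -0.04 and -0.42 (adjusted p = 0.466 and 0.875), with Slc17a7, the main cortical vesicular glutamate transporter, at 0.62 (SE 0.42, adjusted p = 0.338) and 0.30, and Slc17a6 at 1.36 and 1.33. The 8 superficial markers had medians of 0.11 and 0.01 (adjusted p = 0.290 and 0.661). Reln and Calb1, genes of the stellate and pyramidal cells of the superficial layers, had log2 differences of -0.14 (SE 0.45) and 0.14 (SE 0.33) over all libraries and -0.44 and 0.29 with the set in the model. Rorb and Cux1 had -0.59 and 0.68 over all libraries and -0.38 and 0.27 with the set in the model. The 10 deep layer markers had medians of -0.34 and -0.36 (adjusted p = 0.854 and 0.694), with Nxph4 at 1.64 and 1.44 and Etv1 at -0.69 and -0.70. As mean log2 levels per library, the 11 marker groups differed between ages in no case by a two-sided exact permutation test (smallest p = 0.0559, adjusted p = 0.397, for astrocyte markers, 9.94 ± 0.50 in aged and 9.40 ± 0.45 in young libraries, SD, n = 7 each), nor with splits within the library sets (smallest p = 0.0658, adjusted p = 0.333).

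Further groups were called. Antigen presentation and interferon genes were called as higher (15 of 16 positive, medians 0.72 and 0.48, camera adjusted p = 0.000237 and 0.00153, against adjusted p = 0.409 and 0.523 with an estimated correlation), with a median of 1.04 in the Xist-positive and -0.15 in the Xist-negative libraries. Tap2, a peptide transporter, had log2 differences of 1.10 and 0.93 and the class I gene H2-D1 of 0.98 and 0.66. Sterol biosynthesis genes were called as higher (16 of 19 positive, medians 0.29 and 0.35, adjusted p = 0.000292 and 1.068e-05, against adjusted p = 0.276 and 0.400). Fdps had log2 differences of 0.53 and 0.57. Beta protocadherins, clustered adhesion genes, were called as higher (15 of 21 positive, medians 0.40 and 0.34, adjusted p = 0.00124 and 4.929e-07, against adjusted p = 0.276 and 0.294), with Pcdhb9 at 1.24 and 1.40 (limma adjusted p = 0.0792 and 0.0150 over the list alone). Pcdhb5 is listed at 0 in both young Xist-positive libraries, and how reads shared among these similar genes were counted is not given in the sources used here. The ageing brain markers were positive in 13 of 15 genes over all libraries and 8 with the set in the model (medians 0.63 and 0.05, adjusted p = 0.00121 and 0.0375, against adjusted p = 0.276 and 0.523). The apolipoprotein gene Apod had a log2 difference of 1.88 (limma adjusted p = 0.0397 over the list alone) that became 1.70 with the set in the model, where it did not pass (limma adjusted p = 0.138 over the list alone). Spp1 had log2 differences of 1.54 and 1.15, and measured 7470 in aged library 3 against at most 343 in the other aged libraries. The 14 p53 and DNA damage genes were not called (medians 0.03 and -0.05, adjusted p = 0.290 and 0.661), with Bax at 0.46 and 0.13 and Cdkn2a at -1.54 and -0.41.

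The spread of libraries around their group's centre was 210 in aged and 181 in young libraries (log2 units over all genes tested), a difference of 29.1 that a two-sided exact permutation test did not separate from chance (p = 0.222, n = 7 each); with set means removed it was 20.6 (exact p = 0.424). Without young library 2, 1 of the 2 young Xist-positive libraries, the difference was 65.0 (exact p = 0.0379). Without aged library 12, 1 of the 2 aged Xist-negative libraries, it was 1.09 (exact p = 0.968). The difference over all libraries thus depended on single libraries.

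The study's question links expression to recordings. The recording value was 0.101 ± 0.0364 in aged and 0.132 ± 0.0342 in young libraries (SD, n = 7 each), a difference of -0.0306 that was within the spread between libraries (two-sided exact permutation p = 0.129). Within the library sets the difference was -0.0185 (exact permutation p = 0.361). Means were 0.0892 in aged against 0.122 in young Xist-positive libraries and 0.132 against 0.136 in Xist-negative ones. Without young library 16, the lowest young value at 0.0722, the pooled difference was -0.0405 (exact p = 0.0367). Without aged library 3, the lowest aged value at 0.035, it was -0.0196 (exact p = 0.256). No gene was associated with the recording value by limma over all libraries (4618 genes with an unadjusted p under 0.05), with the set in the model (1436), or with age and set (1290). Of 22 correlations between the recording value and 11 genes, taken within each set of 7 libraries, none passed after adjustment (smallest adjusted p = 0.079, exact permutation). Gad1 had r = -0.875 (exact permutation p = 0.007, adjusted p = 0.079; Spearman's rho = -0.821, p = 0.034; r = -0.767 without the 2 libraries farthest from the median) in the Xist-positive and 0.109 (p = 0.821; rho = 0.286) in the Xist-negative libraries.

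**Figure D4:**
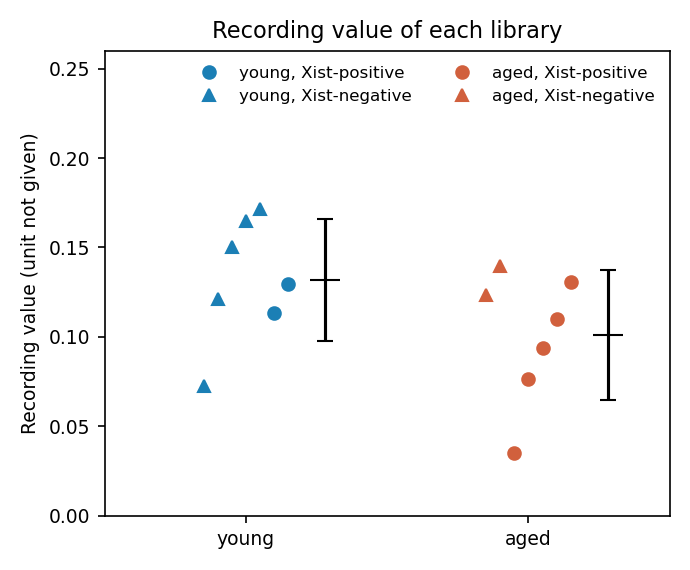
Recording value of each library (vertical axis, unit not given) in the young (blue) and aged (orange) groups, with circles for Xist-positive and triangles for Xist-negative libraries and black bars for the mean ± SD of 7 libraries. Values run from 0.0722 to 0.172 in young and from 0.035 to 0.140 in aged libraries and overlap.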

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

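The screen for libraries far from their group was fixed before values were seen, although some genes it covered were chosen afterwards, and the weighing of the library sets was chosen after seeing results. Dixon's ratio is the gap of the farthest library over the group's range. By chance it passes its critical value of 0.568 for 7 libraries in about 1 in 20 groups, if the 7 are alike. Each age group mixes the 2 library sets, so that rate need not hold here. Aged libraries 12 and 13 and young libraries 2 and 3 form the smaller set of their age group. A flag in these libraries cannot be told apart from the difference between the sets. The ratio passed in 16 of 268 groups tested. Of these, 4 were in aged library 12, which held the lowest aged values of Rnf187 (0.651), Klhdc2 (0.628), Pnrc1 (0.664) and Jund (0.62; log2 value 5.897 against a median of 8.718). Young library 3 held the highest young values of Slc17a7 (0.761) and Bag1 (0.774) and the lowest of Kdr (0.622). Young library 19 held the highest young values of Rorb (0.714) and Col3a1 (0.616) and the lowest of Fzd9 (0.597), which is listed at 0 there. Aged library 3 held the highest aged values of Nxph4 (0.664) and Spp1 (0.628), and young library 2 the lowest young values of Cspg5 (0.593) and Arc (0.609). The antigen presentation and interferon score was highest in aged library 5 (0.586; 9.301 against a median of 6.821), and the astrocyte marker score lowest in aged library 6 (0.591).

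The age comparison was set against other groupings of the libraries, tests fixed before their results were seen except that of the gene lists within the library sets. Of 100 splits of the 14 libraries into 7 and 7, the real one included, 5 called at least 1 gene, with up to 6752 in another split, and 15 called at least 15 gene lists, with up to 25. The 2 splits that called 6752 and 6198 genes came close to separating the library sets, with only 1 Xist-positive library on one side, so these counts point to the structure of the samples. Over all libraries the list count was therefore not beyond chance. The 5 splits for the gene count include those 2, so that test cannot decide whether the gene count was beyond chance. Of 100 splits within the library sets, 3 called at least 2 genes, the count of the real split, which was fewer than the bound set in advance, although another split called 14. The 14 gene lists called with the set in the model were not beyond chance, since 14 of these 100 splits called at least as many, with up to 19 in another. The calls of these 2 genes depended on single libraries, since 0 genes passed with the set in the model and without aged library 3. The Sh3d19 log2 difference was then -1.65 (limma adjusted p = 0.0536) against -1.68 with all libraries, so its call was lost while its size hardly moved.

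The 2 library sets differed in 51.2% of autosomal genes tested, a test written after the sets had been seen. The levels of Xist and of the Y-linked genes in every library follow a difference in sex between the sets, which a preparation batch alone does not produce. For the autosomal genes, effects of sex and of batch cannot be told apart, because every Xist-positive library has a low title number and every Xist-negative one a high number. The labels give neither sex nor batch.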

How the results depend on the processing

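The number of genes called over all libraries, 1 in the main setting, depended strongly on the processing. It was 13048 with sample quality weights (3634 higher and 9414 lower in aged libraries), and 10 when the library set was added to that weighted fit. The 13048 calls therefore cannot be read as age differences apart from the library sets. The count was 52 with equal library totals (50 higher), 5 with upper-quartile scaling and 15 with the stricter filter on low genes. With covariates and no set term it was 4926 for the oligodendrocyte score (4260 lower), 2 for log2 Xist and 6000 for the library total (5071 lower). The cause was not tested in these fits. It was 8405 (6992 lower) with the first principal component of the residuals, against 2 with the library set in the model. That component is orthogonal to age by construction, so it narrows the error and leaves each age difference unchanged. Any part of the difference that comes from the unequal library sets therefore stays in it. The count over all libraries was 41 at an adjusted p under 0.1. It was 0 at an adjusted p under 0.01 or with a minimum fold change of 1.2, as stricter or looser limits give by construction. It stayed at 1 without the filter, with mitochondrial and ribosomal protein genes removed before scaling, and with a pseudocount of 0.1. Leaving out each library gave 0 to 2381 genes. The count was 2381 without aged library 12, 115 without young library 3 and 18 without young library 2. It was 1 without young library 11 or aged library 4, and 0 without any other, young library 16 among them. Aged libraries 12 and 13 are the only aged Xist-negative ones, and young libraries 2 and 3 the only young Xist-positive ones. Without aged library 13 the count was 0, and the cause was not tested.

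Alternatives added after the library sets were seen gave 2 genes with the set in the model, 10 with the set and quality weights, 2 with the set and genes of a mean of 100 or more, 4 with the set and the mitochondrial score, 0 with the set and without aged library 3, 60 in the Xist-positive (58 lower) and 5 in the Xist-negative libraries; the cause was not tested.

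Sh3d19 was lower in aged libraries in every alternative. It lost its call with a minimum fold change of 1.2 (adjusted p = 0.112), at an adjusted p under 0.01, with the set in the model and without aged library 3 (0.0536), and in the Xist-positive (0.126) and Xist-negative (0.323) libraries alone. With each library left out its log2 difference ran from -1.74 to -1.53, and the call was kept in 5 and lost in 9 of 14 cases.

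The 15 gene lists fell to 0 with an estimated correlation and with fry, which allow for the correlation among genes that the preset value does not, and stayed at 13 to 16 with each library left out. Among the alternatives that kept the preset correlation, the astrocyte, chaperone, oxidative phosphorylation and sterol lists were called in 32 of 32, the ribosomal proteins in 31 of 31, and the sodium, calcium and HCN channels in 15 of 32. The median of those channels reversed from 0.17 to -0.19 with log2 Xist as covariate, -0.23 with the set, -0.12 with the set and quality weights, -0.23 with the set and a mean of 100 or more, -0.17 with the set and without aged library 3, -0.20 with the set and the mitochondrial score, -0.29 in the Xist-positive and -0.06 in the Xist-negative libraries. Mitochondrially encoded genes reversed from -0.39 to 0.27 with the set and quality weights and to 0.51 in the Xist-negative libraries, where potassium channels were at -0.12 and presynaptic genes at -0.06. The cause was not tested.

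The share of the authors' 512 genes with the same sign, 93.4% in the main setting, was 76.0% with quality weights, 96.3% with upper-quartile scaling, 88.9% with the oligodendrocyte score and 100% with log2 Xist. It was also 100% in each fit with the set in the model, with quality weights, a mean of 100 or more, the mitochondrial score or aged library 3 left out, and 99.8% in the Xist-positive and 99.8% in the Xist-negative libraries. With each library left out it ran from 88.5% (young library 2) to 97.7% (young library 18); the cause was not tested. Marker scores kept 0 differences in all 14 cases. The difference in spread ran from 1.09 (without aged library 12) to 65.01 (without young library 2, exact p = 0.0379), and that in the recording value from -0.0405 (without young library 16, exact p = 0.0367) to -0.0196; the cause was not tested. Of 3373 gene values, 87 changed sign where neither setting called the gene. No paired analysis was possible because the title numbers of the 2 groups share only the number 3. DESeq2, voom, TMM scaling and surrogate variables were planned and not run, since they need counts, and the unknown depth limits what can be said of genes with low values.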

Other observations

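Nuclear-retained long non-coding RNAs were examined after their values had been seen. With the library set in the model, 7 of 8 had negative log2 differences in aged libraries: Miat (-0.79, SE 0.16), Malat1 (-0.71), Meg3 (-0.63), Kcnq1ot1 (-0.58), Snhg11 (-0.47), Mirg (-0.41) and Rian (-0.33). Neat1, the scaffold of paraspeckles, had one of 0.60. The median over all genes tested in this fit was also negative, at -0.157. None passed by limma (Miat adjusted p = 0.0999), while in the authors' deposited table Miat (adjusted p = 0.000231) and Meg3 (adjusted p = 0.0354) passed and Malat1 did not (adjusted p = 0.0617). Over all libraries Rian, Mirg and Snhg11 had differences of 0.34, 0.17 and 0.16, so the direction depended on the set term.

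The trend with gene span was tested after it had been seen, and the test of the set mix was chosen after its result was seen. Among 15439 genes with a mean of 100 or more, the median log2 difference with the library set in the model fell from 0.13 in the shortest of 5 equal groups of genes (median span 6.3 kb) to -0.22 in the longest (146.4 kb). It went from 0.13 to -0.27 in the Xist-positive and from 0.09 to -0.17 in the Xist-negative libraries. The slope was -0.0614 per doubling of span, and 8 of 441 splits within the sets lay as far from 0 (slopes of the others from -0.0749 to 0.0676), fewer than the bound for chance. At -0.0614 (SD of splits 0.0267) it stayed beyond 2 SD with the set in the model, which argues against the unequal mix of the sets as the whole cause; it was -0.0749 (SD 0.0371) in the Xist-positive libraries and -0.0479 (SD 0.037), within 2 SD of 0, in the Xist-negative ones. Mitochondrial RNA was argued against as the cause, since the slope stayed at -0.0575 (SD of splits 0.0272) with that score in the model. Other causes could not be excluded. The slope was -0.0405 with a nuclear RNA score and -0.0458 with an oligodendrocyte score, each within 2 SD of 0. With transcript length, GC content and expression in the regression it was -0.0837 (SD 0.0438), also within 2 SD of 0. That slope was steeper and its SD larger than without those terms. Lying within 2 SD of 0 therefore does not show that those terms account for the trend. A lower share of nuclear RNA in aged libraries would be a technical source of such a slope, and a biological effect of age on long genes was not separated from it.

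Agreement between the library sets was tested after the set term had been added. Across genes, the age differences of the sets correlated at r = 0.342, and 3 of 21 splits of the Xist-negative libraries gave as high a value (highest other 0.383), so chance was not excluded. After trends with span, length, GC content and expression were removed, r was 0.259 against 0.236 in the next split, which argues against those trends as the whole source.

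A hypothesis stated before its test was that libraries with a lower recording value hold more of the age difference. Within cells of age group and library set, a score of the 512 genes of the authors' deposited table correlated with the recording value at r = -0.022 (exact permutation p = 0.934, 57600 pairings), and at 0.278 (exact p = 0.274) without aged library 3. The test neither favoured nor excluded the hypothesis, because r was near 0 and cells hold only 2 or 5 libraries. What the recording value measures is also not known.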
